A study of Homo sapiens with 26 samples.

How the data were processed

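RNA sequencing counts were taken as deposited for 26 libraries of MCF7 and T47D cells. Per the labels' protocols, MCF7 cells grew in DMEM and T47D cells in RPMI, each with fetal bovine serum, RNA was isolated with an RNeasy kit, and total RNA was sequenced by standard Illumina methods. Per the submitters' processing notes, Trimmomatic, TopHat2, SAMtools and HTSeq were used with the hg38 build, with neither versions nor roles given. The annotation, strand setting, library kit and duplicate handling are not given in the sources used here. Each deposited file held whole-number counts of reads per gene for 1 library, not normalized.

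The files were of 3 kinds. First-set files listed 58037 entries under 56267 gene names, and MK1775 plus alisertib files 23710 gene names. The letter c DMSO files listed 21920 entries under 21459 names, which are the names the other 2 kinds share, and their 186 repeated names each repeated 1 value, which was taken once. Repeated names of the other kinds were summed. Entries that name no gene took 24.28% to 27.49% of the reads in the MK1775 plus alisertib files, of which reads outside any feature were 18.23% to 21.55% of the file, and were left out of library sizes and tests. In the first set 26 gene names had been turned into dates, with 0.1853% of the reads; they stayed in the tests, and none is named. Because the kinds of file differ, the first set of 20 libraries and the second set of 6 were fitted apart. Gene biotypes, positions, lengths and exon numbers came from GENCODE release 29 on GRCh38, matched by symbol, which covered 36085 names of the first and 20984 of the second set.

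Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM normalization, the filterByExpr filter, a mean per group and a robust fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The filter left 18345 genes in the first and 14751 in the second set. The 20 libraries shared 1 estimate of spread, and so did the 6. All adjusted p-values of genes are from this edgeR test, which is two-sided. Log2 fold changes are given ± standard error and levels as CPM, counts scaled to library size, ± SD over the libraries of a group. There were 21 contrasts: RB deletion in DMSO, each treatment against DMSO in each genotype or line, the combination against each single agent, the differences of these effects between genotypes or lines, and the second-set contrasts for MK1775 plus alisertib in each genotype, averaged and as a difference, and for RB deletion over its 6 libraries.

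There were 24 gene lists, tested with camera of limma 3.58.1 with an estimated correlation between genes, adjusted across lists within a contrast. They covered E2F and DNA replication, G2 and mitosis, DNA damage, the RB, cyclin and CDK network, oestrogen response, p53 targets, interferon response, cholesterol synthesis, ATF4 targets and amino acid supply, glycolysis and hypoxia, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, lysosome and autophagy, FOXO and growth factor receptor feedback, luminal, basal, secreted inflammatory, immediate early and histone genes, mitochondrially encoded transcripts, and markers of fibroblasts, immune cells and endothelium. A list of 61 motile cilia genes was added later. The gene lists, contrasts, tests, alternative settings and the rule for named genes were chosen before the data were examined.

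The rule named RB1 in every group, then the genes with the largest absolute log2 fold change among protein-coding genes with adjusted p under 0.05, a mean of at least 2 CPM in the higher group and no overlap between the libraries compared. Up to 8 rising and 8 falling genes were taken for each treatment against DMSO, for RB deletion in DMSO and for the averaged MK1775 plus alisertib effect, and up to 4 each way for the other contrasts. It added 19 fixed cell cycle and hormone receptor genes and up to 4 members with the smallest p of each list described, fewer where space was short, in the same order. ACTB, EEF1A1, MALAT1, KCNQ1OT1 and the cilia genes were chosen after values were seen. PTPRC, from the fixed list of immune markers, was chosen after the interferon result and before its own level was seen. A gene with no read in a group is given as at least N-fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio with its exact 95% counting interval; both cover counting error only.

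The alternative settings chosen then were DESeq2 size factors in the edgeR fit, the Wald test of DESeq2 1.42.0, no filter on low counts, only the libraries of the groups compared, all 22 MCF7 libraries of both sets with the set as a term, the replicate letter as a block, an additive model for the second set, and each library left out in turn. For lists they were camera with a preset correlation of 0.01 and fry. Alternatives added after the data were seen were a correction for gene length and GC content by a spline with 5 degrees of freedom, the combination libraries left out, the first-set DMSO libraries as the control for MK1775 plus alisertib on the names both kinds of file list, and the MK1775 plus alisertib libraries alone, without and with the letters b and c as a block, which was also added to the fit of the 6 second-set libraries.

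Replicate libraries differed by more than sampling noise in every group, with between 10.7% and 49% of genes at an unadjusted p under 0.05 in a chi-square test of counting noise. The edgeR step was tested on simulated counts with known changes. For palbociclib in RB-positive MCF7, over 17350 genes, it recovered 76.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, and called 0.09% of unchanged genes. For the averaged MK1775 plus alisertib effect, over 14299 genes, these were 76.1%, 88.1% and 100%, and for RB-positive cells alone, over 14312 genes, 59.7%, 85.1% and 93.9%. The simulation gave all libraries the same mean per gene apart from the known changes. Its second-set rates therefore do not cover the low levels of abundant genes in the letter c DMSO libraries, described below. It also gave each gene the same spread in all libraries, drew genes independently and held no trend with gene length or GC content. Real pairs differed in noise, so the rates of both sets, false calls included, do not cover the noisier pairs. In simulated data a raised list was called for palbociclib and was not called in either second-set contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.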

Results

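Transcript levels were measured by RNA sequencing in 26 libraries of human breast cancer cell lines, 22 from MCF7 and 4 from T47D. Both lines are luminal and express the oestrogen receptor. MCF7 was studied as RB-positive cells and as a derivative with RB deleted, where RB is the retinoblastoma protein, the repressor of E2F transcription factors that CDK4 and CDK6 inactivate. Cells received DMSO vehicle, the CDK4 and CDK6 inhibitor palbociclib at 250 nM, the mTOR inhibitor everolimus at 500 nM, palbociclib and everolimus together, or the WEE1 inhibitor MK1775 at 200 nM with the Aurora A inhibitor alisertib at 200 nM, for up to 48 h. A first set of 20 libraries formed 10 groups of 2, namely DMSO, palbociclib, everolimus and the combination in each MCF7 genotype, and DMSO and everolimus in RB-positive T47D. A second set of 6 libraries held 2 libraries of MK1775 plus alisertib and 1 DMSO library, titled with the letter c, for each MCF7 genotype. Total counts ran from 15929632 to 32079470 in the first set, from 24705107 to 30038449 in the MK1775 plus alisertib libraries, and from 7466242 to 9766423 in the letter c DMSO libraries. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

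RB1 itself (chromosome 13, 48303726 to 48599436 in GRCh38) was read in every library, including those labelled RB-deleted. In the first set it stood at 16.7 ± 0.393 CPM (SD, n = 2) in RB-deleted DMSO cells and at 66.7 ± 9.77 CPM in RB-positive DMSO cells, a log2 fold change of -2.00 ± 0.13 (standard error; adjusted p = 8.81e-11). The RB-deleted groups held 19.6 ± 5.36 CPM with palbociclib, 17.1 ± 0.839 CPM with everolimus and 30.6 ± 1.21 CPM with the combination. The RB-positive groups held 52.8 ± 7.09, 79.1 ± 2.03 and 85.7 ± 1.38 CPM with the same treatments, and T47D held 101 ± 0.117 CPM with DMSO and 109 ± 2.63 CPM with everolimus. In the second set RB1 was at 48.8 CPM in the RB-deleted DMSO library and 107 CPM in the RB-positive one, and at 49.8 ± 2.39 and 135 ± 8.88 CPM with MK1775 plus alisertib. Gene-level counts do not show which part of RB1 was deleted or whether the transcripts left could be translated.

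The first comparison asked what RB deletion changed in untreated MCF7. Most interferon-stimulated genes were higher and many oestrogen-responsive genes lower in RB-deleted cells, but neither list passed camera with an estimated correlation (adjusted p = 0.0935 for each). IFI27, an interferon-induced mitochondrial protein, stood at 126 ± 8.97 CPM against 6.44 ± 2.65 CPM in RB-positive cells, and the antiviral GTPase MX1 at 38.8 ± 12.1 against 2.51 ± 0.0735 CPM (log2 fold changes 4.26 ± 0.35 and 3.95 ± 0.25). IFIT1, which binds viral RNA, was 11.8-fold higher, at 47 ± 16 CPM. The fatty acid transporter SLC27A6 fell from 19 ± 3.62 to 0.334 ± 0.232 CPM (log2 fold change -5.82 ± 0.28), and the gel-forming mucin MUC5AC fell from 76.4 ± 15.4 to 5.62 ± 1.81 CPM. In all, edgeR called 4382 of 18345 genes, 2018 higher and 2364 lower in RB-deleted cells, of which 354 and 221 differed at least 2-fold.

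IFI44 and IFI44L, both interferon-induced, were read 443 and 135 times over the RB-deleted DMSO pair and 3 and 2 times over the RB-positive pair, ratios of 147 (95% counting interval 50 to 717) and 67.3 (18.3 to 561). The other genes that rose most were the netrin receptor UNC5C (4.54 ± 0.49), the ubiquitin-conjugating enzyme relative UBE2QL1 (4.02 ± 0.23) and ASCL1, a transcription factor of neuroendocrine cells, at 2.99 ± 0.198 against 0.234 ± 0.104 CPM. The glycosyltransferase GALNT5 (-3.80 ± 0.23), the retinoic acid hydroxylase CYP26B1 (-3.19 ± 0.18), AZGP1 (-2.95 ± 0.24), the tight junction protein CLDN1 (-2.65 ± 0.34), IGFBP5 (-2.46 ± 0.13) and the steroid glucuronosyltransferase UGT2B17 (-2.41 ± 0.27) fell most after SLC27A6 and MUC5AC. UGT2B17 has near-identical paralogs, so its count is uncertain. Among cell cycle genes, CCND1, which encodes cyclin D1, fell by 0.65 on the log2 scale (adjusted p = 4.25e-05) and E2F1 fell by 0.46 (adjusted p = 0.000726), while CDK2 (0.35 ± 0.08) and CHEK1 (0.29 ± 0.10) rose. The proliferation marker MKI67 was at -0.37 ± 0.13 (adjusted p = 0.0477), and CCNE1 (0.27 ± 0.11, adjusted p = 0.0867) and MCM2 (-0.17 ± 0.09, adjusted p = 0.172) did not pass.

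Of 47 tested genes of the interferon response and antigen presentation, 41 rose and 1 fell (41 and 1 adjusted over the list alone), with a median of 1.57 (camera adjusted p = 0.0935 with an estimated correlation). BST2, which tethers viruses to the cell surface, rose by 3.16 ± 0.18 and IFITM1 by 1.78 ± 0.14. Of 38 oestrogen-responsive genes 21 fell and 1 rose (25 and 2 adjusted over the list alone; adjusted p = 0.0935 with an estimated correlation), among them the growth factor AREG (-2.35 ± 0.10), STC2 (-0.86 ± 0.10) and TFF1 (-0.87 ± 0.10). The progesterone receptor gene PGR was at -0.55 ± 0.19 and ESR1, the oestrogen receptor, at -0.27 ± 0.10. In the luminal list 13 of 25 genes fell, such as the adherens junction protein CDH1 (-0.75 ± 0.10), and 1 rose (adjusted p = 0.178 with an estimated correlation). E2F and DNA replication genes numbered 10 higher and 1 lower of 48 (adjusted p = 0.363 with an estimated correlation), and G2 and mitosis genes 5 higher and 7 lower of 54 (adjusted p = 0.871 with an estimated correlation).

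Markers of immune cells moved with the interferon genes. Of 8 tested, 4 rose, namely the antigen presentation genes HLA-DRA (1.75 ± 0.29), HLA-DRB1 (0.80 ± 0.14) and CD74 (2.07 ± 0.57), and CD8A (1.11 ± 0.35) (adjusted p = 0.109 with an estimated correlation). Of 8 fibroblast markers 4 rose and 2 fell (adjusted p = 0.374 with an estimated correlation), and the 8 endothelial markers had a median of 0.18 (adjusted p = 0.674 with an estimated correlation). Mitochondrially encoded transcripts, a possible sign of RNA quality, fell in 10 of 15 cases, with a median of -0.43 (adjusted p = 0.381 with an estimated correlation). RNA quality itself was not measured. The other lists gave 10 lower of 23 for immediate early genes (median -0.35), 10 lower of 37 for lysosome and autophagy and 5 lower of 19 for secreted inflammatory genes. Oxidative phosphorylation had 17 higher of 43 and ribosomal proteins 14 of 60, and each of these 5 lists had adjusted p above 0.05 with an estimated correlation. The count of 4382 genes rested on single libraries, falling to 1496 without RB-deleted DMSO library b and to 2402 without RB-positive DMSO library a. It was 2912 with the compared groups fitted alone and 2744 with both sets in 1 fit.

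The second comparison asked what CDK4 and CDK6 inhibition changed in cells with RB. Palbociclib lowered proliferation genes in these cells. The column headers of both treated libraries carry another number after the replicate letter than the sample titles, which were followed, and whether this is only a renaming is not known. RRM2, the small subunit of ribonucleotide reductase, fell from 367 ± 30.2 to 0.655 ± 0.306 CPM (SD, n = 2; log2 fold change -9.11 ± 0.15, adjusted p = 8.35e-23), and KIF20A, a kinesin of cytokinesis, fell from 142 ± 4.62 to 0.324 ± 0.162 CPM. MKI67 was 119-fold lower, the mitotic kinase PLK1 85.1-fold lower, at 2.82 ± 0.107 against 240.5 ± 31.5 CPM, and CCNE2, cyclin E2, 40.3-fold lower. CDK6, a target of the drug, rose 2.49-fold to 44.7 ± 4.07 CPM, and CCND1 rose 1.63-fold. edgeR called 6800 genes, 3264 higher and 3536 lower, of which 574 and 1039 differed at least 2-fold. The larger side depended on the processing: 4794 were higher and 3508 lower with the length and GC correction, 3574 and 3268 with DESeq2 size factors, and 3094 and 2570 with both sets in 1 fit.

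The other genes that fell most were the scaffold IQGAP3 (-9.08 ± 0.29), the activator E2F2 (-7.95 ± 0.27), the kinesin KIF4A (-7.34 ± 0.17), Aurora B, AURKB (-7.28 ± 0.18), and the survivin gene BIRC5 (-7.09 ± 0.15). The DNA glycosylase NEIL3 was read 497 times in the DMSO pair and 3 times in the treated pair, a ratio of 162 (55.1 to 788). Those that rose most were STAT4 (2.73 ± 0.34), the endocytic adaptor STON1 (2.44 ± 0.24), IFIT1 (2.42 ± 0.40), TMEM140 (2.24 ± 0.19), PGM5 (2.13 ± 0.25), the TEAD cofactor VGLL1 (2.09 ± 0.34), the signalling ligand WNT11 (1.99 ± 0.17) and the interferon-induced OAS2 (1.98 ± 0.45). Of the fixed genes, CDK1 (-5.28), TOP2A (-4.84), CHEK1 (-2.93), AURKA (-2.84), E2F1 (-2.78), MCM2 (-1.94), CDK2 (-1.57), CCNE1 (-1.22), CDK4 (-0.76) and WEE1 (-0.55) fell. CDKN1A (-0.08 ± 0.09), MYC (0.09 ± 0.08), ESR1 (-0.20 ± 0.10) and PGR (0.43 ± 0.19) did not pass.

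All 48 E2F and DNA replication genes fell (median -2.58, camera adjusted p = 2.19e-06), such as the thymidine kinase TK1 (-5.27 ± 0.10) and the replication factor MCM10 (-6.84 ± 0.15). All 54 G2 and mitosis genes fell (median -4.90, adjusted p = 1.77e-05). Both counts held when adjusted over the list alone. DNA damage repair and checkpoint genes fell in 38 of 39 cases (adjusted p = 0.00096), among them FANCI (-3.61 ± 0.10) and the exonuclease EXO1 (-5.10 ± 0.15). The RB, cyclin and CDK network held 24 lower and 6 higher of 34 (adjusted p = 0.000362), with MYBL2 at -3.94 ± 0.11 and E2F7 at -5.20 ± 0.18. Lysosome and autophagy genes rose in 22 and fell in 2 of 37 cases (22 and 3 adjusted over the list alone; adjusted p = 0.00258), including the autophagosome proteins GABARAPL1 (1.88 ± 0.14) and WIPI1 (0.87 ± 0.08). Basal and mesenchymal genes rose in 11 and fell in 2 of 22 (adjusted p = 0.0306), including the laminin LAMC2 (1.38 ± 0.09). Interferon genes rose in 33 of 47 cases (37 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), for example BST2 (1.55 ± 0.20). Mitochondrially encoded transcripts rose in 13 of 15 cases (median 0.62, adjusted p = 0.324 with an estimated correlation). They held 2.541% and 3.145% of the counts with palbociclib against 1.801% and 1.67% with DMSO. Whether RNA quality or the drug moved them was not tested.

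**Figure D1:**
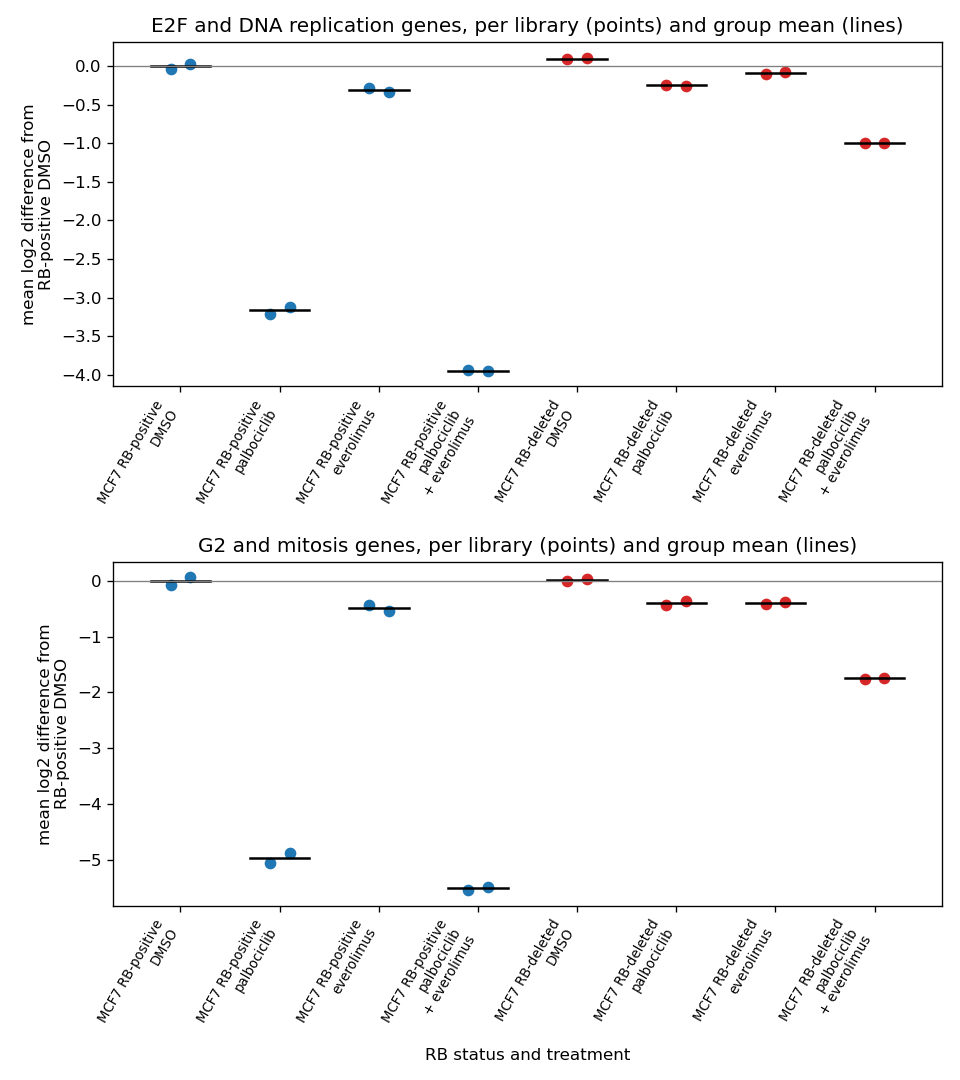
Mean log2 difference from the RB-positive DMSO libraries over the 48 E2F and DNA replication genes (upper panel) and the 54 G2 and mitosis genes (lower panel), one point per MCF7 library of the first set on linear axes, grouped by genotype and treatment. In RB-positive cells the list medians against DMSO were -2.58 and -4.90 with palbociclib, and in RB-deleted cells -0.38 and -0.42.

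In RB-deleted MCF7 palbociclib still lowered cell cycle genes, with a median of -0.38 for E2F and DNA replication genes and -0.42 for G2 and mitosis genes. RRM2 stood at 251 ± 0.746 CPM against 348 ± 14.1 CPM with DMSO, PLK1 fell by 0.42 (adjusted p = 0.00137) and CDK1 by 0.34 (adjusted p = 0.0239) on the log2 scale, and MKI67 was at -0.27 ± 0.13 (adjusted p = 0.195). TGFB2, a secreted growth factor, rose from 6.05 ± 0.614 to 23.4 ± 2.44 CPM (1.95 ± 0.13), and CDK6 rose by 1.18 ± 0.12. Cyclin E1, CCNE1, rose by 0.54 ± 0.11 (adjusted p = 0.00203). edgeR called 2474 genes, 1528 higher and 946 lower, of which 182 and 62 differed at least 2-fold.

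The genes that rose most were the GABA receptor subunit GABRP (2.39 ± 0.26), STAT4 (2.17 ± 0.33), the receptor GLP2R (2.02 ± 0.27), TGFB2, PGM5 (1.87 ± 0.17), AMER2 (1.84 ± 0.23), VGLL1 (1.78 ± 0.27) and the aldehyde dehydrogenase ALDH1A3 (1.77 ± 0.16). Those that fell most were BRINP2 (-1.63 ± 0.30), the receptor GPR19 (-1.29 ± 0.28), the AP-1 subunit FOSL1 (-1.22 ± 0.29), CHST8 (-1.17 ± 0.22), RNFT2 (-1.16 ± 0.22) and ASCL1 (-1.10 ± 0.24). E2F and DNA replication genes fell in 29 and rose in 1 of 48 cases (36 and 2 adjusted over the list alone; median -0.38, adjusted p = 0.00124), including MCM10 (-0.88 ± 0.09) and the origin subunit ORC1 (-1.01 ± 0.11). G2 and mitosis genes fell in 39 of 54 (adjusted p = 0.0039), including the securin gene PTTG1 (-0.69 ± 0.09) and AURKB (-0.73 ± 0.10), and ribosome biogenesis genes in 10 of 40 (adjusted p = 0.0278). Basal and mesenchymal genes rose in 10 of 22 (median 0.60, adjusted p = 0.00131), including LAMC2 (0.81 ± 0.09) and the caveolae protein CAV2 (0.72 ± 0.08), and lysosome genes in 10 of 37 (adjusted p = 0.0498). Interferon genes rose in 25 of 47 (37 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation). Mitochondrially encoded transcripts rose in 6 of 15 cases (median 0.26, adjusted p = 0.448 with an estimated correlation), from 1.395% and 1.272% to 1.697% and 1.887% of the counts. The count of 2474 fell to 253 with these groups fitted alone, to 937 without RB-deleted DMSO library b and to 1344 without palbociclib library b, and was 4032 without palbociclib library a.

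The test of the difference between genotypes asked which palbociclib responses depended on RB. The cell cycle genes separated the genotypes: the palbociclib effect on RRM2 was 8.64 ± 0.18 log2 units higher in RB-deleted than in RB-positive cells (adjusted p = 1.43e-20), that on PLK1 5.99 ± 0.14 and that on MKI67 6.62 ± 0.23 higher. IQGAP3 (9.03 ± 0.35), KIF20A (8.29 ± 0.22) and E2F2 (7.20 ± 0.34) completed the largest positive differences. The iodide transporter SLC5A5 (-2.96 ± 0.49), the kinase JAK3 (-1.89 ± 0.36) and the glucuronosyltransferase UGT2B15 (-1.71 ± 0.26) gave negative ones, while the differences for CDK6 (-0.14 ± 0.16) and CCND1 (-0.32 ± 0.14) did not pass. All 48 E2F and DNA replication genes (median 2.26, adjusted p = 2.36e-07) and all 54 G2 and mitosis genes (median 4.63, adjusted p = 1.26e-06) had a positive difference. So did 35 of 39 DNA damage genes (adjusted p = 0.000338) and 21 of 34 network genes (adjusted p = 3.35e-05), with 2 of these negative. Of 37 lysosome genes 7 had a negative difference (adjusted p = 0.0127), including the galactosidase GLA (-0.71 ± 0.12). In all 2356 genes differed, 1645 positive and 711 negative. The 4 groups fitted alone gave 1072 (895 and 177), both sets in 1 fit 2158 (1147 and 1011), and a correction for gene length and GC content 3939 (1885 and 2054).

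The next comparison asked what mTOR inhibition changed. In RB-positive MCF7 everolimus lowered genes of ribosome biogenesis, cholesterol synthesis, amino acid supply and mitosis, and raised some p53 targets. BMF, a promoter of apoptosis, rose from 5.52 ± 0.0157 to 29.8 ± 2.69 CPM (SD, n = 2; 2.43 ± 0.12, adjusted p = 1.31e-12), and KLHL24, a FOXO target, from 14.3 ± 1.38 to 56.2 ± 2.09 CPM. PLK1 fell from 240.5 ± 31.5 to 113 ± 3.58 CPM (-1.09 ± 0.08), and SLC7A5, the large neutral amino acid transporter, fell by 1.51 on the log2 scale (adjusted p = 1.74e-10). MYC rose by 0.65 ± 0.08, CDK6 by 0.94 ± 0.12 and WEE1 by 0.62 ± 0.09. CDKN1A was at 207.7 ± 19.7 CPM with DMSO and 224.5 ± 18.2 CPM with everolimus, and the libraries overlapped. edgeR called 5631 genes, 2686 higher and 2945 lower, of which 433 and 259 differed at least 2-fold.

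The other genes that rose most were the cathepsin CTSO (2.38 ± 0.29), YPEL1 (2.28 ± 0.17), ANKRD33B (2.06 ± 0.18), PGM5 (1.84 ± 0.26), TGFB2 (1.77 ± 0.12) and TBX4 (1.74 ± 0.32). Those that fell most were the neuropeptide gene GAL (-2.48 ± 0.21), the actin-binding CORO1A (-2.30 ± 0.16), DPF1 (-2.19 ± 0.24), the peroxisomal oxidase ACOX2 (-2.19 ± 0.23) and the histone HIST1H2BJ (-2.10 ± 0.14), a member of a family of near-identical copies. Ribosome biogenesis genes fell in 35 and rose in 1 of 40 cases (median -0.52, adjusted p = 0.00132), including the rRNA methyltransferase NOP2 (-0.96 ± 0.08) and NOP16 (-0.97 ± 0.10). Cholesterol synthesis genes fell in 23 of 33 (adjusted p = 0.00132), including the desaturase SCD (-1.03 ± 0.10) and the reductase DHCR7 (-0.86 ± 0.09). ATF4 target and amino acid genes fell in 23 and rose in 4 of 40 (adjusted p = 0.0192), including the serine synthesis enzyme PHGDH (-1.02 ± 0.11). G2 and mitosis genes fell in 45 of 54 (median -0.46, adjusted p = 0.009) and E2F genes in 30 of 48, with 1 rising (adjusted p = 0.00857). Of 34 p53 targets 11 rose and 4 fell (adjusted p = 0.0171), led by the antiproliferative BTG2 (1.45 ± 0.08). FOXO and growth factor receptor genes rose in 19 of 25 (adjusted p = 0.0996 with an estimated correlation), including TXNIP (1.49 ± 0.10). Ribosomal protein genes rose in 47 of 60 (adjusted p = 0.299 with an estimated correlation), including RPL10 (0.71 ± 0.09). Transcripts encoded by mitochondria rose in 8 and fell in 1 of 15 cases (median 0.36, adjusted p = 0.459 with an estimated correlation), from 1.801% and 1.67% to 2.311% and 2.689% of the counts. Without everolimus library a the count was 3539.

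In RB-deleted MCF7 everolimus raised TGFB2 from 6.05 ± 0.614 to 41.2 ± 2.98 CPM (2.77 ± 0.13, adjusted p = 8.06e-13) and MYC by 0.87 ± 0.08, and lowered ASCL1 from 2.99 ± 0.198 to 0.336 ± 0.0137 CPM (-3.13 ± 0.32). PLK1 fell by 0.54 (adjusted p = 2.84e-05) and AURKA, Aurora A, by 0.72 on the log2 scale (adjusted p = 6.5e-07), while MKI67 (-0.08 ± 0.13) and MCM2 (0.01 ± 0.09) did not pass. The other genes that rose most were PSG5 (2.56 ± 0.33), ANKRD33B (2.48 ± 0.17), the calcium channel subunit CACNG6 (2.40 ± 0.24), ALDH1A3 (2.29 ± 0.15) and YPEL1 (2.27 ± 0.19). Those that fell most were the growth factor BMP5 (-2.90 ± 0.35), HIST1H2BJ (-2.46 ± 0.14), GAL (-2.18 ± 0.17) and TEX14 (-2.07 ± 0.26). Ribosome biogenesis (32 lower of 40), cholesterol synthesis (24 of 33) and G2 and mitosis genes (42 of 54) fell (adjusted p = 0.00159, 0.00159 and 0.0198), including UTP20 (-0.89 ± 0.10), SCD (-1.11 ± 0.10) and CCNB1, cyclin B1 (-0.85 ± 0.10). Replication-dependent histone genes fell in 16 of 26 cases (median -0.78, adjusted p = 0.00159). Basal and mesenchymal genes rose in 12 of 22 (median 0.94, adjusted p = 0.00159), including the caveolae protein CAV1 (1.42 ± 0.10) and the matrix protein TGFBI (1.14 ± 0.12). E2F genes fell in 16 of 48 (adjusted p = 0.0611 with an estimated correlation). Mitochondrially encoded transcripts rose in 9 and fell in 1 of 15 cases (median 0.42, adjusted p = 0.35 with an estimated correlation), from 1.395% and 1.272% to 1.801% and 2.29% of the counts. edgeR called 5793 genes, 3032 higher and 2761 lower, against 3622 without RB-deleted DMSO library b and 3717 without everolimus library b. DESeq2 size factors turned the split to 2835 higher and 2965 lower.

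Few genes passed the edgeR threshold for a difference between genotypes in the everolimus response, but 3194 of 18345 had an unadjusted p under 0.05. The transglutaminase TGM2 (1.69 ± 0.17, adjusted p = 7.45e-06), the hair keratin KRT81 (1.94 ± 0.42), the transcriptional repressor SNAI2 (1.59 ± 0.34) and the uroplakin UPK3A (1.57 ± 0.36) had the largest positive differences, and ZNF233 (-1.63 ± 0.33), the death ligand TNFSF10 (-1.56 ± 0.31) and CLEC2D (-1.27 ± 0.23) the largest negative ones. TGM2 stood at 9.66 ± 0.474 CPM with DMSO and 41.6 ± 3.77 CPM with everolimus in RB-deleted cells, and at 14.4 ± 2.78 and 19.1 ± 0.29 CPM in RB-positive cells. Of the fixed genes PLK1 passed (0.54 ± 0.12, adjusted p = 0.0192). Histone genes had 5 negative differences of 26 (adjusted p = 0.00596), led by HIST1H2BD (-0.71 ± 0.13), and basal genes 3 positive of 22 (adjusted p = 0.0162), led by the fibronectin gene FN1 (0.91 ± 0.14). The total of 227 genes, 165 positive and 62 negative, was unstable, and ranged from 44 to 2020 when 1 library was left out. It was 44 without RB-positive everolimus library a, 149 without library b, 56 and 2020 without RB-positive DMSO libraries a and b. It was 126 and 69 without RB-deleted DMSO libraries a and b, and 68 and 94 without RB-deleted everolimus libraries a and b. It was 536 with no count filter, 368 (229 and 139) with DESeq2, 111 with these groups fitted alone, 87 (48 and 39) with both sets in 1 fit and 108 with the combination libraries left out.

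Adding the inhibitors together asked what they changed against DMSO and against each alone. Whether their joint effect exceeds the sum of the single effects was not tested. The combination libraries stood apart from the other first-set MCF7 libraries, with MALAT1 at 832 to 1128 CPM against 32.8 to 75.5 CPM. Drug effects and a difference between library batches therefore cannot be told apart in these comparisons. In RB-positive MCF7 the combination lowered proliferation genes, some of them to a few counts. RRM2 stood at 0.463 ± 0.0283 CPM against 367 ± 30.2 CPM with DMSO (SD, n = 2; -9.63 ± 0.17, adjusted p = 9.52e-23), the replication factor CDC45 at 0.157 ± 0.0341 against 55 ± 0.485 CPM, and E2F1 fell by 5.62 on the log2 scale (adjusted p = 4.55e-20). KLHL24 rose 11-fold to 158 ± 4.8 CPM and CDK6 rose by 2.03 ± 0.12, and PGR rose by 0.85 ± 0.19. edgeR called 11134 genes, 5424 higher and 5710 lower, of which 2091 and 2228 differed at least 2-fold.

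ERCC6L, a helicase of mitotic chromosomes, was read 1818 times in the DMSO pair and 1 time in the treated pair, a ratio of 1240 (223 to 49100). GTSE1 was read 1926 and 3 times (439, 150 to 2130) and E2F2 1833 and 3 times (418, 143 to 2030). GPR19 was at least 26.7-fold lower, having no read after treatment against a floor of 3 counts over the group. The separase ESPL1 (-8.43 ± 0.27) and the kinetochore protein NDC80 (-8.26 ± 0.24) also fell. The genes that rose most were ZBTB20 (4.81 ± 0.48), KLHL24, CCDC146 (3.21 ± 0.32), MYO15B (3.16 ± 0.21), the basal transcription factor TP63 (3.12 ± 0.29), STON1 (3.11 ± 0.23), PGM5 (3.11 ± 0.24) and CREBRF (3.10 ± 0.14). All 48 E2F genes (median -3.28, adjusted p = 0.000386) and all 54 mitosis genes (median -5.96, adjusted p = 0.0017) fell, with 35 of 39 DNA damage genes (adjusted p = 0.0154). So did 25 of 33 cholesterol genes (adjusted p = 0.00756), 28 of 40 ATF4 target and amino acid genes (adjusted p = 0.0189) and 33 of 40 ribosome biogenesis genes (adjusted p = 0.0174). Examples were the cholesterol enzyme EBP (-1.99 ± 0.11), PHGDH (-3.94 ± 0.15), SLC7A5 (-2.86 ± 0.11) and BOP1 (-1.94 ± 0.12). FOXO and growth factor receptor genes rose in 21 of 25 (adjusted p = 0.134 with an estimated correlation). Transcripts encoded by mitochondria rose in 10 of 15 cases (median 0.53, adjusted p = 0.61 with an estimated correlation), from 1.801% and 1.67% to 2.729% and 3.055% of the counts. The length and GC correction gave 11024 genes, 6657 higher and 4367 lower, and DESeq2 size factors 5710 and 5494.

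In RB-deleted MCF7 the combination also lowered proliferation genes, by less. PLK1 fell from 228 ± 9.07 to 31.4 ± 0.499 CPM (-2.86 ± 0.09, adjusted p = 1.13e-16), AURKA by 2.28, CDK1 by 1.98, E2F1 by 1.47 and MKI67 by 1.01 on the log2 scale. TGFB2 rose from 6.05 ± 0.614 to 78.8 ± 0.00182 CPM (3.70 ± 0.13), KLHL24 by 3.29 ± 0.11 and CDK6 by 2.21 ± 0.12. The other genes that rose most were the lysine catabolism enzyme AASS (3.59 ± 0.28), the retinal transporter ABCA4 (3.53 ± 0.32), NCF2 (3.39 ± 0.33) and the plasminogen activator inhibitor SERPINE1 (3.26 ± 0.37). Those that fell most were GAL (-3.57 ± 0.21), CORO1A (-3.56 ± 0.18), HIST1H2BJ (-3.41 ± 0.16), ASCL1 (-3.38 ± 0.34) and the centromere protein CENPM (-3.08 ± 0.14). E2F genes fell in 42 of 48 (median -1.10, adjusted p = 0.00136) and mitosis genes in 51 of 54 (median -1.83, adjusted p = 0.00226). Cholesterol genes fell in 26 of 33 (adjusted p = 0.00429) and ATF4 target and amino acid genes in 29 of 40 (adjusted p = 0.0252). Basal genes rose in 11 of 22 (adjusted p = 0.0243), and oxidative phosphorylation genes fell in 39 of 43 (adjusted p = 0.183 with an estimated correlation), including COX8A (-1.99 ± 0.10). Mitochondrially encoded transcripts rose in 11 of 15 cases (median 0.67, adjusted p = 0.476 with an estimated correlation), from 1.395% and 1.272% to 2.575% and 2.517% of the counts. edgeR called 11040 genes, 5472 higher and 5568 lower, against 5639 and 5400 with DESeq2 size factors. In the 4 combination libraries, which stood apart from the other MCF7 libraries of the first set, the nuclear RNA MALAT1 was at 832 to 1128 CPM against 32.8 to 75.5 CPM, and KCNQ1OT1 at 45.6 to 52.2 against 14.6 to 18.9 CPM.

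Against palbociclib alone, genes of cholesterol synthesis were lower with the combination in RB-positive cells. A difference between library batches cannot be told apart from the added drug in any comparison with a single agent. IFI27 fell from 24 ± 12.7 to 1.81 ± 0.256 CPM (-3.71 ± 0.47), the keratin KRT13 from 43.2 ± 1.45 to 3.4 ± 0.739 CPM (-3.69 ± 0.14) and E2F1 by 2.85 on the log2 scale (adjusted p = 8.05e-12), while the ephrin receptor EPHA4 rose from 5.85 ± 0.359 to 51.4 ± 0.415 CPM. Interferon genes fell in 38 and rose in 1 of 47 (median -1.35, adjusted p = 0.184 with an estimated correlation). E2F genes fell in 30 and rose in 4 of 48 (adjusted p = 0.0339). Cholesterol genes fell in 24 of 33 (adjusted p = 0.00388) and ATF4 target and amino acid genes in 28 of 40 (adjusted p = 0.0339). Glycolysis and hypoxia genes fell in 25 of 33 (adjusted p = 0.0339), including ENO1 (-1.62 ± 0.09) and LDHA (-1.74 ± 0.10). In RB-deleted cells the same step lowered 42 of 48 E2F genes (adjusted p = 0.00171) and 50 of 54 mitosis genes (median -1.39, adjusted p = 0.00171), with TK1 at -2.20 ± 0.09 and PLK1 at -2.44 ± 0.09, and 26 of 33 cholesterol genes (adjusted p = 0.00171). CORO1A fell by 3.25, KRT13 by 3.13 and HLA-DRA by 3.04 on the log2 scale in RB-deleted cells. Against everolimus alone, all 48 E2F genes fell in RB-positive cells (median -3.00, adjusted p = 0.000116), with SYCE2 at least 45.9-fold and GPR19 at least 45.5-fold lower, and the gap junction gene GJA1 (3.08 ± 0.20) and the deiodinase DIO2 (3.06 ± 0.16) rose. In RB-deleted cells 41 of 48 E2F genes fell (adjusted p = 0.00214), including TK1 (-2.74 ± 0.09), and ANKRD12 (2.55 ± 0.13) rose. edgeR called 9932 and 9774 genes against palbociclib and 8960 and 10162 against everolimus in RB-positive and RB-deleted cells. The length and GC correction turned the split of 4134 higher and 4826 lower in RB-positive cells against everolimus to 5723 and 3125.

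The combination effects of the genotypes differed in the cell cycle genes. The difference was 7.94 ± 0.20 for RRM2 (adjusted p = 1.66e-18), 6.20 ± 0.25 for MKI67, 4.52 ± 0.17 for PLK1 and 4.16 ± 0.19 for E2F1, each higher in RB-deleted cells. All 48 E2F genes (median 2.16, adjusted p = 9.1e-07) and all 54 mitosis genes (median 3.84, adjusted p = 7.33e-06) had positive differences, with 33 of 39 DNA damage genes (adjusted p = 0.00055) and 19 of 34 network genes (adjusted p = 6.47e-05). Interferon genes had 17 positive differences of 47 (30 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), led by OAS3 (2.43 ± 0.25) and OAS1 (1.46 ± 0.25). Histone genes had 8 negative and 1 positive of 26 (adjusted p = 0.00488). UNC5C (-3.31 ± 0.75), KLHL4 (-2.20 ± 0.33), UBE2QL1 (-1.89 ± 0.34) and GJA1 (-1.69 ± 0.23) had the largest negative differences, while ERCC6L stood at 7.73 ± 0.884 CPM in RB-deleted and 0.0302 CPM in RB-positive cells with the combination. Of 1833 genes 1344 were positive and 489 negative, and the length and GC correction turned this to 1124 and 2024 of 3148. The count was 1071 with both sets in 1 fit and between 960 and 1067 without RB-deleted combination library a (960), RB-deleted DMSO library b (1022), or RB-positive combination library a (1041) or b (1067).

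**Figure D2:**
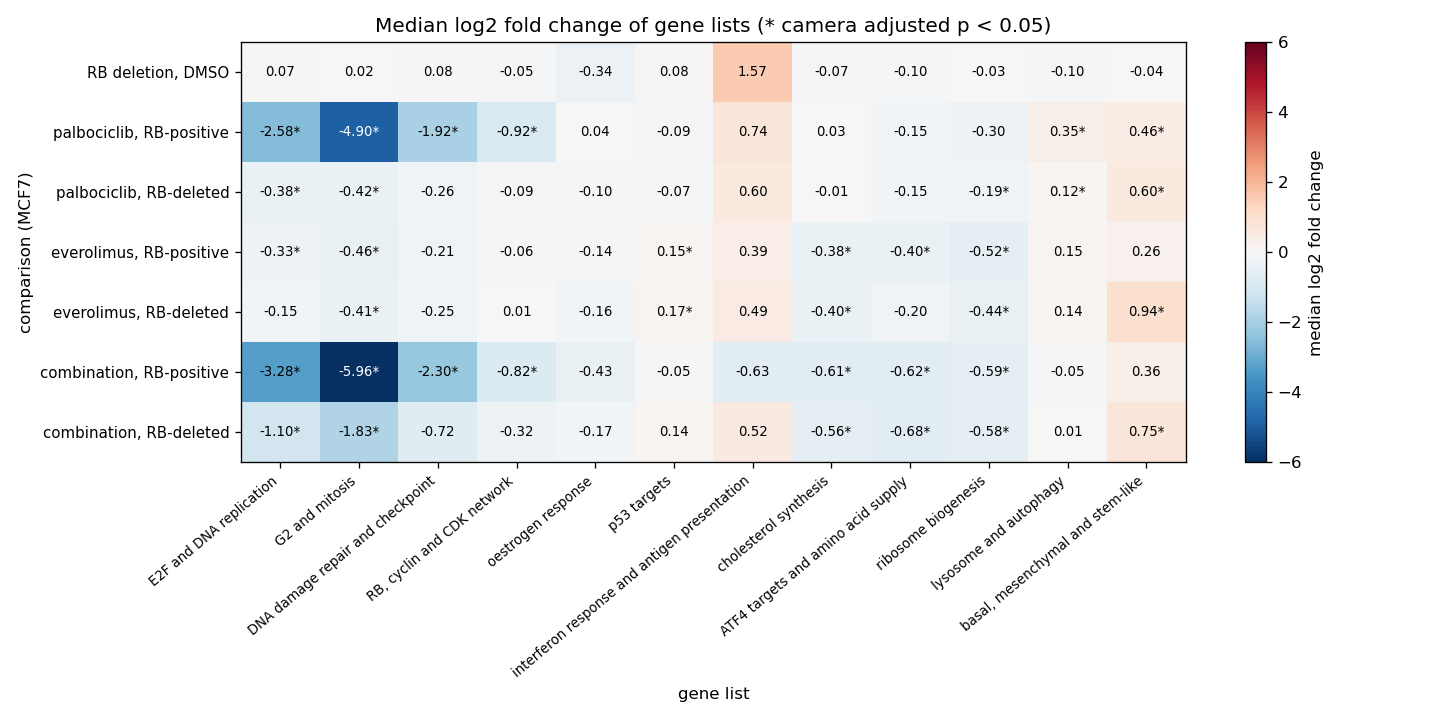
Median log2 fold change of 12 gene lists (horizontal) in 7 comparisons of treated with DMSO libraries or of RB-deleted with RB-positive DMSO cells (vertical), as colour from blue (lower) to red (higher), with the value printed in each cell and an asterisk where the camera adjusted p with an estimated correlation was under 0.05. The G2 and mitosis list ran from -5.96 with the combination in RB-positive cells to 0.02 for RB deletion in DMSO.

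T47D asked whether the everolimus response held in a second RB-positive line. Everolimus lowered proliferation and cholesterol genes there as well and raised a group of genes that includes parts of motile cilia. The fall of ribosome biogenesis genes seen in MCF7 was absent from their mean in T47D. Against RB-positive MCF7 with DMSO, that mean was -0.522 and -0.541 log2 units with DMSO. With everolimus it was -0.518 and -0.535. CDC20B, a relative of the anaphase activator in multiciliated cells, rose from 11.7 ± 0.193 to 261 ± 18.9 CPM (SD, n = 2; 4.48 ± 0.15, adjusted p = 8.63e-14), and CFAP126, a ciliary protein, from 0.706 ± 0.177 to 19.2 ± 1.02 CPM. MYC rose by 0.96 ± 0.08 and CDK6 by 0.85 ± 0.15, while CCND1 fell from 439 ± 15.6 to 234 ± 0.487 CPM and PLK1 from 168 ± 2.6 to 77.6 ± 3.85 CPM. edgeR called 5405 genes, 2769 higher and 2636 lower, of which 699 and 406 differed at least 2-fold.

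The other genes that rose most were the chemokine receptor ACKR3 (5.06 ± 0.31), the prostaglandin receptor PTGER2, read 96 times against 3 (34.2, 11.3 to 169), the axonemal CFAP52 (4.62 ± 0.46) and TEKT1 (4.28 ± 0.32), the transcription factor FOXN4 (4.39 ± 0.28) and RASSF2 (4.30 ± 0.47). Those that fell most were the MAPK-induced transcription factors ETV4 (-4.03 ± 0.45) and EGR3 (-3.15 ± 0.25), the integrin ITGB6 (-2.98 ± 0.18), EIF4E1B (-2.82 ± 0.29) and the organic anion transporter SLCO4A1 (-2.75 ± 0.26). TOP2A (-0.97), AURKA (-0.87), CHEK1 (-0.76), MKI67 (-0.71), CDK2 (-0.66), E2F1 (-0.57) and MCM2 (-0.55) fell, and PGR (0.46 ± 0.18) and ESR1 (-0.09 ± 0.10) did not pass. G2 and mitosis genes fell in 53 of 54 (median -0.86, adjusted p = 0.000815), E2F genes in 43 of 48 (adjusted p = 0.000642) and DNA damage genes in 30 of 39 (adjusted p = 0.0401). Cholesterol genes fell in 24 of 33 (median -0.59, adjusted p = 0.000339), including INSIG1 (-1.60 ± 0.09) and SCD (-1.45 ± 0.10). Glycolysis and hypoxia genes fell in 23 of 33 (adjusted p = 0.0401), including LDHA (-1.04 ± 0.10), and p53 targets in 16 of 34, with 4 rising (adjusted p = 0.0403). Transcripts encoded by mitochondria rose in 8 of 15 cases (median 0.42, adjusted p = 0.52 with an estimated correlation), from 2.019% and 2.219% to 2.827% and 2.573% of the counts. The T47D groups fitted alone gave 8146 genes, and 3549 and 3559 were called without DMSO libraries a and b. DESeq2 size factors turned the split to 2697 higher and 2728 lower.

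The everolimus effects of T47D and RB-positive MCF7, which grew in different media, differed for 2591 genes, 1358 higher and 1233 lower in T47D. BTG2 fell in T47D and rose in MCF7 (difference -2.35 ± 0.12, adjusted p = 8.82e-12), and CCND1 had a difference of -0.97 ± 0.14 and WEE1 of -0.76 ± 0.13. NOP2 (1.06 ± 0.12) was among the 24 of 40 ribosome biogenesis genes with a positive difference (median 0.47, adjusted p = 0.00164). BTG2 and the repair protein DDB2 (-0.97 ± 0.13) were among the 13 of 34 p53 targets with a negative one (adjusted p = 0.00164). CYP26B1 had no read in T47D with DMSO and 1.19 ± 0.139 CPM with everolimus, and stood at 9.76 ± 1.62 and 11.2 ± 0.00783 CPM in MCF7. CDC20B was read 3 times or fewer in each MCF7 pair. The count was 1582 without RB-positive MCF7 everolimus library a, 1610 without T47D DMSO library b, 1635 without T47D everolimus library a, and 4055 with the length and GC correction.

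**Figure D3:**
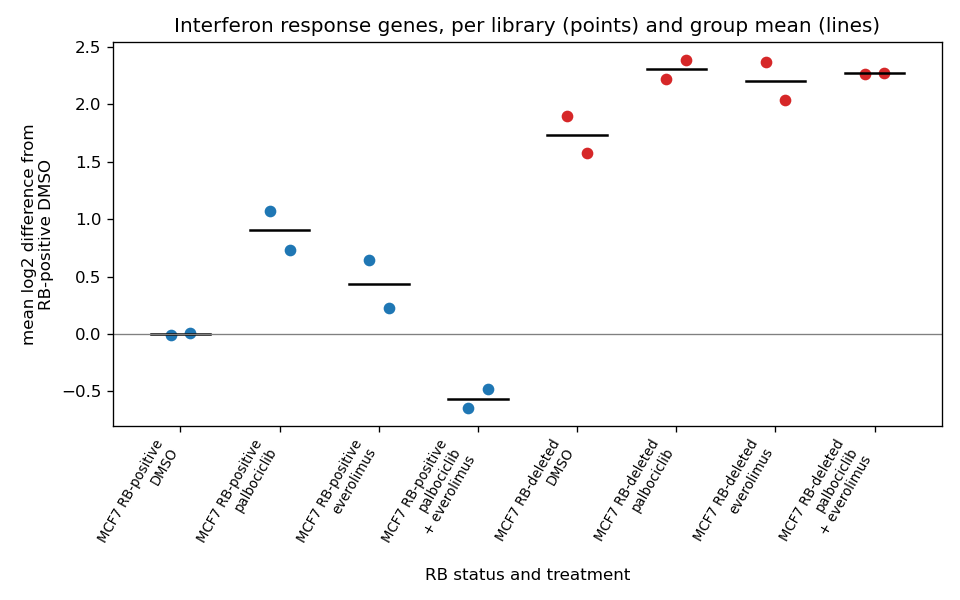
Mean log2 difference from the RB-positive DMSO libraries over the 47 interferon response and antigen presentation genes, one point per MCF7 library of the first set on a linear axis, grouped by genotype and treatment. The median difference between genotypes over the list was 1.57 in DMSO, 1.38 with palbociclib, 1.51 with everolimus and 2.66 with the combination.

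The second set asked what blocking WEE1 and Aurora A changed in each genotype, with a single letter c DMSO library as control for each, so the treated pairs alone give the spread. These DMSO libraries differed from all others in level for abundant genes. ACTB stood at 138 to 173 CPM against 4874 to 5931 CPM in the treated and 3493 to 6705 CPM in the first-set MCF7 libraries. EEF1A1 stood at 11.63 to 11.98 CPM against 726.5 to 840.3 and 8374 to 16880 CPM. MALAT1 was at 269 to 292 CPM in them and 934.5 to 1503 CPM in the treated libraries. Genes that moved the same way against the letter c and against the first-set DMSO libraries are therefore given first. Both comparisons share the treated libraries, which also differ from the first set in kind of file, so agreement between them is not independent support. Averaged over genotypes, the CDK inhibitor gene CDKN1A rose from 106 to 589 ± 27.7 CPM in RB-positive and from 129 to 936 ± 11.6 CPM in RB-deleted cells (2.67 ± 0.06, adjusted p = 3.69e-44; 1.31 ± 0.07 against the first-set DMSO libraries). MDM2, the p53 ubiquitin ligase, rose by 2.37 ± 0.06 (2.06 ± 0.07). MKI67 fell from 524 to 268 ± 5.25 and from 578 to 156 ± 6.7 CPM (-1.43 ± 0.05; -1.14 ± 0.07), and E2F1 (-1.21 ± 0.08; -1.26 ± 0.08) and CHEK1 (-1.17 ± 0.10; -1.03 ± 0.09) fell. PGR fell against the letter c control alone (-1.09 ± 0.06; -0.08 ± 0.08). The signal transducer STAT1 (2.24 ± 0.06; 1.04 ± 0.07) and IFIT1 (4.33 ± 0.12; 2.10 ± 0.16) rose.

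Of 33 tested p53 targets 28 rose and 2 fell (adjusted p = 0.182 with an estimated correlation), against 27 and 5 with the first-set control (adjusted p = 0.0257). G2 and mitosis genes fell in 39 and rose in 7 of 53 (median -0.99, adjusted p = 0.182 with an estimated correlation). They did so in 50 and 2 cases with the first-set control (median -1.53, adjusted p = 0.0936 with an estimated correlation), including CENPF (-1.36 ± 0.06; -0.36 ± 0.08) and the passenger protein INCENP (-1.49 ± 0.07; -0.98 ± 0.08). E2F genes fell in 35 and rose in 6 of 48 (adjusted p = 0.301 with an estimated correlation). They did so in 45 and 1 with the first-set control (adjusted p = 0.0257), including E2F2 (-2.29 ± 0.09; -1.42 ± 0.09) and MCM10 (-1.70 ± 0.08; -1.75 ± 0.08). The replication clamp PCNA and MCM7 rose against the letter c and fell against the first-set control (1.79 ± 0.07; -1.86 ± 0.07 and 1.14 ± 0.05; -1.46 ± 0.07). Of the fixed genes, CDK4 turned in the same way in RB-positive (1.49 ± 0.08; -1.37 ± 0.09) and RB-deleted cells (1.51 ± 0.08; -1.30 ± 0.09), as on average did TOP2A (0.24 ± 0.05; -1.08 ± 0.07), CDK2 (0.19 ± 0.06; -1.11 ± 0.07) and ESR1 (0.13 ± 0.05; -0.69 ± 0.07). Against the letter c control the genotypes did not move alike. ESR1 went from 336.8 to 485.4 CPM in RB-positive and from 352.4 to 294.1 CPM in RB-deleted cells. In the same order TOP2A went from 257.5 to 377.4 and from 299 to 282.6 CPM, and CDK2 from 90.03 to 88.38 and from 110.6 to 145.8 CPM. The treated RB-positive libraries held CDK2 at 86.09 and 90.66 CPM, on both sides of the control. On average PLK1 (0.09 ± 0.06; -1.65 ± 0.07), AURKA (0.10 ± 0.06; -1.68 ± 0.07), CDK1 (-0.11 ± 0.08; -1.74 ± 0.08), MCM2 (-0.02 ± 0.05; -1.23 ± 0.07) and MYC (0.10 ± 0.07; -0.20 ± 0.07) fell, and WEE1 rose (-0.04 ± 0.08; 0.40 ± 0.08), against the first-set control alone. This need not hold for each genotype. Against the letter c control PLK1 went from 103.4 to 144.3 CPM in RB-positive and from 118.7 to 96.54 CPM in RB-deleted cells. In the same order AURKA went from 97.32 to 129.6 and from 104.2 to 90 CPM, and CDK1 from 57.77 to 67.18 and from 66.15 to 48.82 CPM. CCND1 rose against both controls in RB-deleted cells (2.38 ± 0.08; 0.68 ± 0.09), but against the letter c control alone in RB-positive cells (2.74 ± 0.08; 0.10 ± 0.09). Interferon genes rose in 42 and fell in 4 of 47 (adjusted p = 0.341 with an estimated correlation), against 34 and 7 (adjusted p = 0.414 with an estimated correlation). Ribosomal protein genes were higher in 59 of 60 against the letter c control (median 3.86) and lower in all 60 against the first-set control (median -1.95). The medians of the oxidative phosphorylation (1.09 and -1.30) and luminal lists (1.70 and -0.48) turned as well.

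The rule for the largest changes picked genes with few or no reads in 1 group, which the control decides. PGAM4 (at least 29.8-fold and 23.1-fold in RB-positive and RB-deleted cells), F8A1 (at least 92.8-fold in RB-positive cells) and, in RB-deleted cells, the interferon-induced TRIM22 (at least 15.3-fold), UBD (at least 12.8-fold) and the chemokine CXCL10 (at least 7.64-fold) were higher. PRPS1L1 (at least 60.5-fold and 53.9-fold), BOD1L2 (at least 35.1-fold and 41.2-fold) and, in RB-deleted cells, PAPOLB (at least 106-fold) were lower; PGAM4, F8A1, PRPS1L1, BOD1L2 and PAPOLB have near-identical relatives, so their counts are uncertain. edgeR called 9977 of 14751 genes on average, 4811 higher and 5166 lower (4995 and 4921 with DESeq2 size factors), 8897 in RB-positive and 7974 in RB-deleted cells. Of 14025 genes tested with both controls, 2490 were higher and 2479 lower with both, 3128 had opposite calls and 4917 were called with 1 control alone.

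The genotypes differed in the response to MK1775 plus alisertib for 1799 genes, 565 with a higher and 1234 with a lower effect in RB-deleted cells, with 1 DMSO library per genotype. Of 14025 genes tested with both controls, 420 had a higher and 520 a lower effect with both, 20 had opposite calls and 2810 were called with 1 control alone. MKI67 (-0.92 ± 0.10, adjusted p = 5.84e-10; -0.42 ± 0.14 with the first-set control), PGR (-1.03 ± 0.12; -0.65 ± 0.16), PLK1 (-0.78 ± 0.12; -0.51 ± 0.14) and TOP2A (-0.63 ± 0.10; -0.40 ± 0.13) had lower effects, and CCNE2 (1.07 ± 0.19; 1.02 ± 0.18), the pro-apoptotic BBC3 (1.34 ± 0.18; 1.36 ± 0.19) and OAS3 (1.77 ± 0.11; 1.32 ± 0.21) higher ones. Of the fixed genes, CCND1 had opposite calls with the controls (-0.35 ± 0.10; 0.58 ± 0.13). RB1 (-0.30 ± 0.14; 0.55 ± 0.16), E2F1 (0.41 ± 0.16; 0.75 ± 0.16), MCM2 (0.30 ± 0.11; 0.70 ± 0.14) and WEE1 (0.40 ± 0.16; 0.50 ± 0.16) passed with the first-set control alone. Among the genes with the largest differences, the gap junction gene GJA1 had a lower effect with both controls (-2.77 ± 0.42; -3.88 ± 0.29). The cilia regulator FOXJ1 had a higher one with the letter c control alone (4.38 ± 1.33; 1.15 ± 2.52). Of 53 G2 and mitosis genes 40 had a lower effect (48 adjusted over the list alone; median -0.77, adjusted p = 0.185 with an estimated correlation), and 42 with the first-set control (median -0.68, adjusted p = 0.0612 with an estimated correlation). The oestrogen response list had a median of -0.55 with the letter c and 0.03 with the first-set control. The count was 1155 (186 and 969) with DESeq2, 2735 (1394 and 1341) with both sets in 1 fit, 2933 (1545 and 1388) with the first-set control and 962 without RB-deleted MK1775 plus alisertib library b.

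Across the 6 libraries of the second set the genotypes differed for 2247 genes, 1280 higher and 967 lower in RB-deleted cells. IFI27 (4.48 ± 0.14, adjusted p = 1.24e-33), MX1 (3.34 ± 0.13) and IFIT1 (3.77 ± 0.14) were higher, SLC27A6 (-5.62 ± 0.24) and PGR (-0.68 ± 0.06) lower, and CCNE2 (0.68 ± 0.09) and CDKN1A (0.48 ± 0.06) were higher. Of 47 interferon genes 42 rose (median 1.62, adjusted p = 0.208 with an estimated correlation). Of 33 p53 targets 16 rose (adjusted p = 0.208 with an estimated correlation), and of 53 mitosis genes 31 fell and 1 rose (adjusted p = 0.208 with an estimated correlation). The count was 1189 with DESeq2, 1173 with an additive model, 3770 with both sets in 1 fit and 4964 (2397 and 2567) from the MK1775 plus alisertib libraries alone.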

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

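The tests of gene length and GC content for the combination, of both explanations for the letter c libraries, of paralogs, and of library batches for the interferon genes were chosen only after the result was seen.

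Every contrast that tests a difference between effects picked out genes whose effects differ by the edgeR test of the difference itself. There were 2356 genes for palbociclib between genotypes, 227 for everolimus between genotypes, 1833 for the combination between genotypes, 2591 for everolimus between T47D and RB-positive MCF7, and 1799 for MK1775 plus alisertib between genotypes. The differences below are in log2 units, and those for MK1775 plus alisertib rest on 1 letter c DMSO library per genotype.

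For palbociclib, the RB-deleted minus RB-positive difference was 9.03 for IQGAP3, 8.64 for RRM2, 8.29 for KIF20A, 7.20 for E2F2, 6.62 for MKI67 and 5.99 for PLK1, and -2.96 for SLC5A5, -1.89 for JAK3, -1.71 for UGT2B15 and -0.71 for GLA. For everolimus it was 1.94 for KRT81, 1.69 for TGM2, 1.59 for SNAI2, 1.57 for UPK3A, 0.91 for FN1 and 0.54 for PLK1, and -1.63 for ZNF233, -1.56 for TNFSF10, -1.27 for CLEC2D and -0.71 for HIST1H2BD. For the combination it was 7.94 for RRM2, 6.20 for MKI67, 4.52 for PLK1, 4.16 for E2F1, 2.43 for OAS3 and 1.46 for OAS1, and -3.31 for UNC5C, -2.20 for KLHL4, -1.89 for UBE2QL1 and -1.69 for GJA1.

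Between T47D and RB-positive MCF7, the everolimus difference was 1.06 for NOP2, and -2.35 for BTG2, -0.97 for CCND1, -0.97 for DDB2 and -0.76 for WEE1; the lines also differ in medium. For MK1775 plus alisertib between genotypes it was 4.38 for FOXJ1 (not past the threshold with the first-set control, at 1.15, adjusted p = 0.81), 1.77 for OAS3, 1.34 for BBC3 and 1.07 for CCNE2, and -2.77 for GJA1, -1.03 for PGR, -0.92 for MKI67, -0.78 for PLK1 and -0.63 for TOP2A, and -0.35 for CCND1, which was 0.58 with the first-set control.

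The 4 combination libraries stood apart from the other first-set MCF7 libraries. A trend with gene length and GC content stays open. After its correction 9070 genes differed from palbociclib in RB-positive cells, against 9932 before. That count cannot decide, because an effect of everolimus could keep it high. Everolimus against DMSO gave 6797 genes in these cells with the same correction, which also raised that count, from 5631. A difference between library batches stays open: outside the cell cycle lists, the shift of the combination libraries correlated across genes with that of the MK1775 plus alisertib libraries, with no library in common, at Pearson 0.41 and 0.429 in the 2 genotypes. MALAT1 was high in both, at 832 to 1128 and 934.5 to 1503 CPM. KCNQ1OT1 was high in the combination libraries alone, at 45.6 to 52.2 CPM against 12.47 to 15.79 CPM with MK1775 plus alisertib. In T47D, KCNQ1OT1 went from 18.52 and 19.23 CPM with DMSO to 29.88 and 29.54 CPM with everolimus. Everolimus acting in the combination stays open as well, since adding it to palbociclib correlated across genes with everolimus against DMSO at 0.347 and 0.476. Genes are not independent replicates, and these may contribute together.

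Abundant genes were far lower in the letter c DMSO libraries than in all others. Treatment cannot explain the gap between the letter c and the first-set DMSO libraries, because neither was treated. ACTB stood at 138 to 173.1 CPM in the letter c and at 4748 to 6705 CPM in the first-set MCF7 DMSO libraries. The highest reads per base were 3.19 to 4.69 in the letter c and 159 to 640 in all first-set libraries. Whether treatment also raised ribosomal protein genes stays open. Against the first-set DMSO libraries their median was -1.95, but this cannot decide, because the treated libraries differ from the first set in kind of file. EEF1A1, also abundant, stood at 726.5 to 840.3 CPM in the treated and 8374 to 16880 CPM in the first-set MCF7 libraries. Counts limited per position in the letter c files stay open as well. Over 10424 genes, the difference of the RB-deleted letter c library from the first-set DMSO libraries fell with reads per base, at a Spearman correlation across genes of -0.707. Reads per base also measure abundance, so this correlation restates the pattern. It cannot tell such a limit from another loss of abundant transcripts. Reads shared between paralogs or pseudogenes may explain genes read in the letter c libraries and nearly absent after treatment, since 19% of the 100 protein-coding genes that fell most had 1 exon, against 2.22% of all tested. No biological explanation was tested for these genes.

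Most interferon genes were higher in RB-deleted cells. The list passed camera with an estimated correlation with everolimus and the combination (adjusted p = 0.0385 and 0.0042), but not with DMSO, palbociclib or MK1775 plus alisertib (adjusted p = 0.0935, 0.163 and 0.136). Gene length and GC content are argued against by a list median of 1.58 after the correction, a batch confined to the DMSO libraries by medians of 1.38 to 2.66 in the 4 other treatments, and immune cells in the cultures by PTPRC at 0 CPM in the RB-deleted DMSO libraries, against 0.0321 CPM in the RB-positive ones. An effect of RB loss on these genes stays a hypothesis, because the labels do not say how many RB-deleted clones were used, and a difference between the lines that arose apart from RB was not tested. In the second set, 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 1173 genes in the additive model, as the 1 split with so many, and the highest of the others gave 0.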

How the results depend on the processing

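The length and GC correction, the fit without the combination libraries, the first-set DMSO control and the fit of the MK1775 plus alisertib libraries alone were chosen only after the data were seen. Over the named genes and all alternatives, 3500 of 3653 values kept their direction and side of the threshold, 109 no longer passed, 30 newly passed and 14 reversed. With DESeq2 size factors all 306 named values kept theirs, but with the first-set DMSO control for MK1775 plus alisertib only 20 of 41 did and 13 reversed. Many named genes were chosen for large changes that passed, so such shares are partly built in. Where a count changed below, the cause was not tested. Fits with fewer libraries have fewer to estimate the spread from.

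With only the libraries compared, the count was 2912 for RB deletion in DMSO (4382 in the reported fit), 253 for palbociclib in RB-deleted cells (2474; 189 higher and 64 lower), 1072 for the palbociclib difference (2356), 111 for the everolimus difference (227) and 8146 for everolimus in T47D (5405). With the MCF7 libraries of both sets it was 2744 for RB deletion in DMSO, 87 for the everolimus difference, 1071 for the combination difference (1833), 2735 for the MK1775 plus alisertib difference (1799) and 3770 for RB deletion in the second set (2247). It split into 919 higher and 887 lower for palbociclib in RB-deleted cells, and into 1147 and 1011 for the palbociclib difference. With the DESeq2 Wald test it was 368 for the everolimus difference, 1155 for the MK1775 plus alisertib difference and 1189 for RB deletion in the second set. With no filter on low counts it was 536 for the everolimus difference. Fewer libraries alone do not account for the rise from 5405 to 8146 in T47D. In the chi-square test of counting noise, 49% of genes had an unadjusted p under 0.05 in the RB-deleted palbociclib pair. In the T47D DMSO and everolimus pairs 11.6% and 20.6% did. An estimate of spread shared by all pairs runs too low for noisy pairs and too high for tight ones. The reported p-values thus lean low for palbociclib in RB-deleted cells and high for everolimus in T47D.

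With the length and GC correction the count was 3939 for the palbociclib difference, 3148 for the combination difference and 4055 for the T47D difference (2591). For the combination in RB-positive cells it split into 6657 higher and 4367 lower, against everolimus into 5723 and 3125, and for the everolimus difference into 150 and 90. The median of all genes went to 0.126 for the combination in RB-positive cells (0 before) and to 0.109 against everolimus (-0.03 before), so the first 2 splits lie partly in that shift. The ribosomal protein median turned from -0.29 to 0.11 for the combination in RB-deleted cells, and the histone median from -0.16 to 0.39 in RB-positive cells. Without the combination libraries the everolimus difference had 108 genes.

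Which side of a split was larger, higher or lower, turned under at least 1 setting in 15 of the 21 contrasts, so near-even splits carry little weight. It turned in 9 of 16 contrasts with the length and GC correction, 8 of 21 with DESeq2 size factors and with the DESeq2 Wald test alike, 5 of 19 with the MCF7 libraries of both sets and 4 of 4 with the first-set control. It turned in 2 of 21 with no count filter, 2 of 16 with only the libraries compared, 3 of 21 when 1 library was left out, and in 0 of 21 with the replicate block. The length and GC correction gave 5201 higher and 3869 lower for the combination against palbociclib in RB-positive cells (4841 and 5091 in the reported fit), and 4312 and 4003 against everolimus in RB-deleted cells (4680 and 5482). DESeq2 size factors gave 4495 and 4340 for MK1775 plus alisertib in RB-positive cells (4263 and 4634) and 4013 and 3897 in RB-deleted cells (3936 and 4038).

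Leaving out 1 library gave 1496 to 4680 genes for RB deletion in DMSO, 937 to 4032 for palbociclib in RB-deleted cells, 3539 to 5209 and 3622 to 4663 for everolimus in RB-positive and RB-deleted cells, 44 to 2020 for the everolimus difference, 960 to 2475 for the combination difference, 3549 to 3684 for everolimus in T47D, 1582 to 3044 for the T47D difference and 962 to 2622 for the MK1775 plus alisertib difference. The lone library of a group was then assumed to vary like the other groups.

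With the first-set DMSO control the MK1775 plus alisertib difference had 2933 genes, and the median of all genes in RB-deleted cells went to 0.108 (0.002 with the letter c control). Against that control the averaged effect was -1.46 for MCM7, -1.86 for PCNA, -1.08 for TOP2A, -1.65 for PLK1, -1.68 for AURKA, -1.11 for CDK2, -0.69 for ESR1 and -0.20 for MYC, which were above 0 against the letter c control, and 0.40 for WEE1, which was below 0. CDK4 turned to -1.37 in RB-positive and -1.30 in RB-deleted cells. The difference between genotypes turned to 0.58 for CCND1 and 0.55 for RB1, and for CCND1 to 0.28 with the MCF7 libraries of both sets. RB deletion in the second set had 1173 genes in the additive model and 4964 from the MK1775 plus alisertib libraries alone. Of the list tests 73 passed with an estimated correlation, 257 with the preset correlation and 319 with fry, which does not compare a list with other genes.

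The letters a and b were tested as a replicate block. Over 45 pairs of groups the deviations of libraries with the same letter correlated at -0.551 to 0.388 (median 0.013). They were over 0.1 in 13 pairs and under -0.1 in 13, so the letter marked no consistent pairing. Pairing or batches within part of the groups are not excluded. The block gave 4312 genes for RB deletion in DMSO and 231 for the everolimus difference, and no count moved by over 1.5 times. In the second set the MK1775 plus alisertib groups share 2 letters, b and c. Their deviations correlated at -0.043, and the replicate block, added after the data were seen, gave 4760 genes for RB deletion in these libraries, against 4964 without it. A replicate block over all 6 libraries, also added then, leaves 1 residual degree of freedom. It gave 8464 genes for MK1775 plus alisertib in RB-positive and 7513 in RB-deleted cells, 9335 on average, 1643 for the difference and 2106 for RB deletion. The DMSO groups there are single libraries, of 7466242 and 9766423 counts.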

Other observations

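The cilia list was written only after the T47D genes that rose most were seen, and its prediction before its test; it leaves those genes out. Everolimus may raise a wider set of motile cilia genes in T47D. Of 61 listed genes 47 were tested there and 42 rose, with a median log2 fold change of 1.92 (camera p = 1.61e-08 with an estimated correlation). FOXJ1, the regulator of motile cilia genes, rose from 6.46 to 122.5 CPM, and MCIDAS, which starts the multiciliated cell programme, from 3.95 to 15.4 CPM. The cyclin-like CCNO rose from 19.5 to 76.8 CPM, HYDIN by 4.02 and RSPH4A by 3.82 on the log2 scale.

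In MCF7, by limma's camera with an estimated correlation, the same list had 12 genes higher and 3 lower in RB-positive cells (median 0.48, camera p = 0.0145) and 12 higher and 4 lower in RB-deleted cells (median 0.40, camera p = 0.0429). The difference between T47D and RB-positive MCF7 was positive for 17 genes, with a median of 1.30 (camera p = 1.01e-05 with an estimated correlation). The list was chosen from the same libraries that tested it, so it stays a hypothesis, and whether cilia formed was not measured.

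Interferon genes were higher in RB-deleted than in RB-positive cells under each of the 5 treatments, in 41, 37, 41, 43 and 45 of 47 genes with DMSO, palbociclib, everolimus, the combination and MK1775 plus alisertib. The camera adjusted p with an estimated correlation was 0.0935, 0.163, 0.0385, 0.0042 and 0.136 in that order.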
